A study of Mus musculus with 24 samples.

How the data were processed

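Gene expression was measured by RNA sequencing in 24 liver samples from male B6C3F1 mice given dichloroacetic acid (DCA) in their drinking water at 0, 1, 2 or 3.5 g/L, with 6 samples per dose. Per the labels' protocols, RNA came from about 20 mg of frozen liver of mixed lobes, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. That kit keeps strand information, but whether the counting used it is not given in the sources used here. Antisense and overlapping genes may therefore share reads. The labels give 6 samples per dose and do not say in words that each came from its own mouse, so p-values measure the spread between these samples.

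The values used were RPKM (reads scaled by the length of the gene model and by the mapped reads of the library) per gene and library, as the authors deposited them in 1 table for the whole series. The submitters' processing notes name CASAVA, STAR 2.4, Partek and the mouse build mm10, without saying which step each one served. The gene annotation behind the deposited RPKM is not given in the sources used here. Zeros stand in the deposited table as 1e-04 RPKM. The table as held is in order of gene symbol and stops inside the line for Olfr272, so that line was dropped. Genes later in that order, including all Pdk, Scd, Slc and Ugt genes, were not analysed here. A further 13 lines whose symbols had turned into dates were dropped, which left 15582 genes. Every sample had its own column, and no column was left unused.

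Depth was estimated from the deposited values, because a gene's RPKM in a library is a whole multiple of what 1 read is worth. Of 2115 candidate genes at low values, 1683 whose values all lay near whole multiples were kept. Over these, 20450 of 20525 values (99.6%) came out whole within 0.02 times their number of reads. The selection itself favours so high a share. The estimate gave relative depths of 0.94 to 1.118 between libraries. Combined with annotated gene lengths it gave about 23,800,000 to 28,300,000 reads per library, an approximate figure whose median of 25,300,000 had an interquartile range of 18,600,000 to 28,800,000 over genes. In simulated libraries of 14580 genes the relative depth was recovered from 1715 genes with a largest error of 0.004%, tested only for totals within a narrow range around those seen here. Counts were not recovered for all genes, so no test on counts was run.

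Genes at 0.5 RPKM or more in at least 6 libraries were tested, which kept 6540 genes. Values were taken as log2(RPKM + 1), and limma 3.58.1 in R 4.3.3 fitted 1 mean per dose to all 24 libraries, with a spread that depended on expression level. All tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Each dose was compared with control and with the other doses, and a linear slope over dose was fitted. A log2 fold here is a difference of log2(RPKM + 1) and understates the change of genes at low RPKM. Standard errors (SE) come from limma, and standard deviations (SD) are over the 6 libraries of a dose. Sample titles carry a tag, L1, L2 or L3, whose meaning the labels do not state. All controls are tagged L1, 1 g/L has 3 libraries of L1 and 3 of L2, 2 g/L is all L2, and 3.5 g/L is all L3. The tag was therefore left out of the model and used in alternatives, and at 3.5 g/L it cannot be told apart from dose. Replicate numbers are not shared between doses, so no pairing was fitted.

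Gene lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the lists, where at least 5 members were tested. Of 52 lists with 1250 entries, 821 entries were in the table, 6 of them under an older or newer symbol, and 390 fall after its last symbol. This left 43 lists tested. Beside each list stand its members that passed the test over all genes, its members that passed when adjusted over the list alone, and camera's adjusted p with a correlation estimated for each list. Camera was tested on simulated data in which 1 list was shifted by 0.5 on the log2 scale, over 20 runs of the comparison of 2 g/L with control. With the preset correlation it called that list in 20 runs, but also a mean of 7.9 and at most 13 of the lists that had not been shifted. With an estimated correlation it called the shifted list in 9 runs and no other. Groups of genes are therefore described by counts of members, which are to be read against the counts over all tested genes. Members can move together across libraries, so such counts do not allow for correlation between genes either and are descriptions, not tests.

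The test for single genes was also run on simulated data, with 100 genes changed 1.5-fold and 100 changed 2-fold among the 6540. The changed genes were drawn from those with a mean log2(RPKM + 1) above 1. For 1 g/L against control it recovered 91% and 97% of these, with 7 false calls among 6340 unchanged genes. For 2 g/L against control it recovered 90% and 100%, with 3 false calls. For 3.5 g/L against control it recovered 94% and 97%, with 17 false calls.

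Genes to be named were chosen by a rule. It takes the 8 largest rises and 8 largest falls at each dose among called genes with a mean of at least 1 RPKM in 1 of the groups, leaving out predicted, clone, microRNA and small nucleolar names. It adds the 3 called members with the smallest adjusted p of each called list, 22 genes named in advance, and the 3 largest rises and falls of each comparison between doses and of the slope. This gave 120 genes, of which 2 are not reported here. Of the 22 genes named in advance, 6 were not in the table as held and 2 were below the filter. The rule, the lists, the tests and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Where any other gene is named, its values had been seen first.

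Alternatives were a pseudocount of 0.1 RPKM, no filter, a filter of 2 RPKM, library factors by median ratio, quantile normalization, a robust spread, a minimum fold of 1.5, only the 2 groups compared in the fit, the tag as a term over 0, 1 and 2 g/L, comparisons within 1 tag, dose rank in place of dose, other set tests, and leaving out each library in turn. Correlations of fold changes between doses were set against 100 simulations of unchanged groups sharing the same controls, and repeated over 20 splits of the controls. Gene positions are those of a GENCODE annotation of GRCm38 (mm10), and 15482 of the 15596 symbols in the table matched a reference symbol or synonym. Calculations also used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.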

Results

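Liver RNA was sequenced from male B6C3F1 mice, a hybrid strain, that drank water with dichloroacetic acid (DCA), a by-product of water chlorination that inhibits pyruvate dehydrogenase kinase, for 6 days. The mice were 4 weeks old. The doses were 0 (control), 1, 2 and 3.5 g/L, with 6 libraries each, 24 in all. Depth, estimated from the steps between low values, was about 23,800,000 to 28,300,000 reads per library, and relative depth ranged from 0.94 to 1.118. Within a dose, pairs of libraries correlated across genes at r = 0.9788 to 0.9949 (60 pairs). Values are RPKM, and a log2 fold is the limma difference of log2(RPKM + 1) with n = 6 per dose. The design compares liver expression over dose after 6 days.

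Expression followed dose along the first principal component, which held 51.8% of the variance. Control libraries lay at −19.8 to −16.6 on it, 1 g/L at −14.5 to −8.1, 2 g/L at 2.5 to 17.5 and 3.5 g/L at 14.3 to 21.8. Within 1 g/L the libraries with title tag L1 lay at −14.5 to −12 and those with L2 at −12.7 to −8.1. Tag and dose are thus only partly told apart on it. The second component (8.9%) set 2 g/L (−14.1 to −2.2) apart from 3.5 g/L (2.8 to 11.3). Fat-oxidation genes driven by the nuclear receptor PPARα, led by Cyp4a14, Cyp4a10 and Ehhadh, rose at 2 and 3.5 g/L, while Lpin1, a phosphatidate phosphatase and transcriptional coactivator, fell at every dose. Of 6540 genes tested, limma called 744 at 1 g/L (546 rose, 198 fell), 3395 at 2 g/L (2738 rose, 657 fell) and 3368 at 3.5 g/L (2525 rose, 843 fell).

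**Figure D1:**
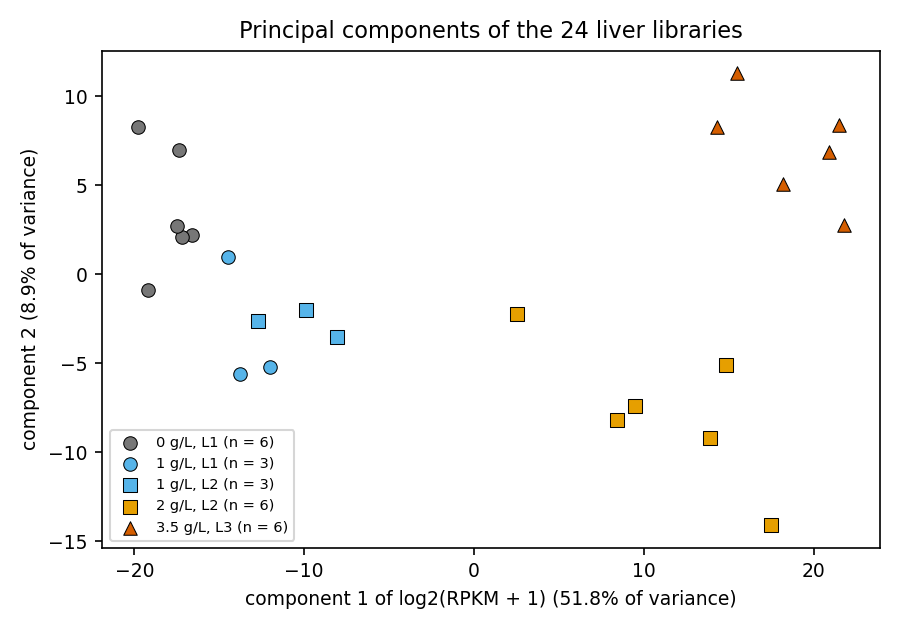
Principal components 1 and 2 of log2(RPKM + 1) for the 24 libraries, 1 point per library, coloured by dose and shaped by title tag. Control libraries lie at −19.8 to −16.6 on component 1 and 3.5 g/L libraries at 14.3 to 21.8.

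The balance of rises and falls is relative to the scaling used. The median log2 fold of all tested genes was 0.05 at 1 g/L, 0.12 at 2 g/L and 0.10 at 3.5 g/L as deposited. With library factors by median ratio, rises made up 40.7%, 50.2% and 50.2% of the calls at 1, 2 and 3.5 g/L, against 73.4%, 80.6% and 75% as deposited. Quantile normalization gave 52.4%, 51% and 49.7%. Both methods centre the folds, which moves the shares towards 50%, so these shares do not show which scaling is right. Small changes in the direction of the shift are thus relative to it, and larger ones are described first here.

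**Figure D2:**
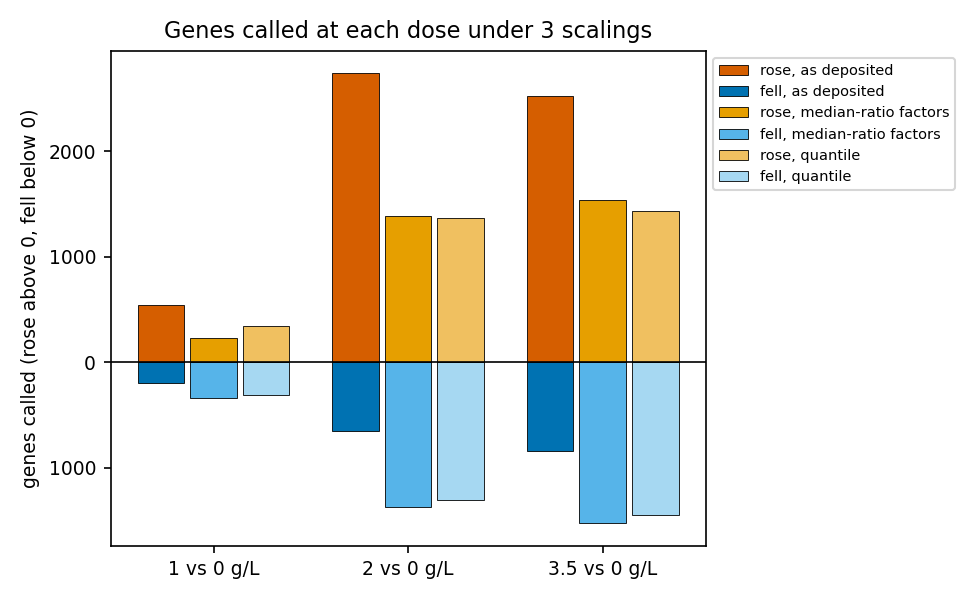
Number of genes called higher (up) and lower (down) than control at 1, 2 and 3.5 g/L under 3 scalings: as deposited, median-ratio factors and quantile normalization. At 2 g/L rises were 80.6% of calls as deposited and 50.2% with median-ratio factors.

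At 1 g/L the largest fall was in Lpin1, from 50.4 ± 16.9 to 7.90 ± 2.17 RPKM (SD, n = 6), a log2 fold of −2.52 (SE 0.19, adjusted p = 1.79e-08). Lpin1 lies on chromosome 12 (GRCm38) at 16535669 to 16610966. Other large falls were in Hspa1b (−1.64, SE 0.27) and Hspa1a (−1.004, SE 0.187), which encode inducible cytosolic heat shock proteins and are near-identical, so that their reads are uncertain. Bhlhe40, a repressor in the circadian clock, fell (−1.30, SE 0.23), as did Fkbp5, a glucocorticoid-induced co-chaperone (−1.08, SE 0.13), and complement component C4b (−0.96, SE 0.12). Among the rises were Egr1, an immediate early transcription factor (1.74, SE 0.33), Nr1d1, the clock repressor REV-ERBα (0.992, SE 0.165), and Apoc2, the cofactor of lipoprotein lipase (0.69, SE 0.08). Mup20, the urinary pheromone darcin, rose by 1.59 (SE 0.45), Arrdc3 by 1.26 (SE 0.32), the water channel Aqp8 by 0.81 (SE 0.21), the ubiquitin ligase Mid1 by 0.84 (SE 0.22), and the histone gene Hist1h3h by 0.71 (SE 0.20). Mup and histone genes share reads with near-identical copies and are uncertain.

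With the title tag (L1 or L2) as a term, Lpin1 (−2.70), Egr1 (2.26), Bhlhe40 (−1.39), Fkbp5 (−1.13), Herpud1 (−1.21), C4b (−0.89), Nr1d1 (0.88), Apoc2 (0.70) and Hspa1b (−1.30) stayed called at 1 g/L, and the count over all genes was 92 in place of 744. The term made the median SE over genes 1.25 times as large at 1 g/L and 1.77 times as large at 2 g/L, so a call can end at a like fold. Mup20 (1.82, SE 0.54), Arrdc3 (1.37, SE 0.36), Mid1 (1.01, SE 0.26), Aqp8 (0.73, SE 0.28), Hspa1a (−1, SE 0.26) and Derl3 (−0.89, SE 0.37) were then no longer called at much the same folds, and Hist1h3h at a smaller one (0.40, SE 0.23). Within L1 alone, with 3 treated libraries, 50 genes were called. Leaving out control 3 gave 456 calls, leaving out 1 g/L 52 gave 476 and leaving out 1 g/L 54 gave 484.

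**Figure D3:**
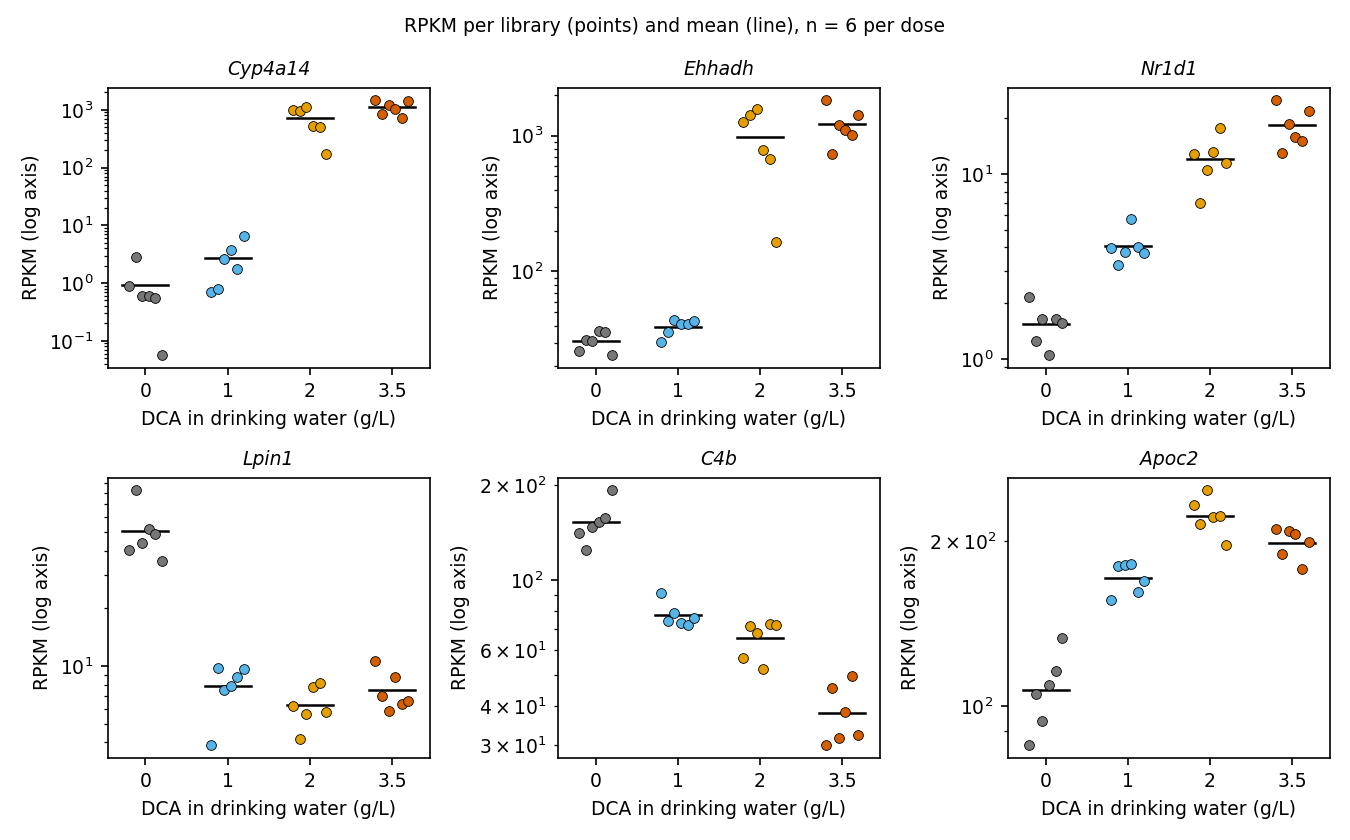
RPKM per library (points) and mean (line) of 6 genes at 0, 1, 2 and 3.5 g/L, on log axes, n = 6 per dose. Lpin1 fell from a mean of 50.4 to 7.90 RPKM at 1 g/L, while Cyp4a14 had means of 0.925, 2.69, 714 and 1120 RPKM over the doses.

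Gene groups are given as lists with counts of members, because camera also called a mean of 7.9 and at most 13 unshifted lists in simulated data. Counts of members do not allow for members that move together and are no test of a list. These counts stand against all 6540 tested genes, of which 546, 2738 and 2525 rose at 1, 2 and 3.5 g/L. Falls over all genes were 198, 657 and 843. With median-ratio factors falls made up a larger share of all calls (rises were 50.2% at 2 g/L, against 80.6% as deposited). Fall counts of a list under those factors therefore stand against a higher background. A list whose share is near that of all genes does not stand apart. Of 43 lists camera called 10 at 1 g/L, 19 at 2 g/L and 18 at 3.5 g/L. With an estimated correlation camera called 0 lists at each dose, with 0, 4 and 5 at an unadjusted p under 0.05. Nuclear genes of oxidative phosphorylation were the group with most rises at 1 g/L. Of 52 members, 20 rose and none fell (31 rose adjusted over the list alone), with ATP synthase subunits Atp5l (0.34, SE 0.06) and Atp5k (0.37, SE 0.08) and complex I subunit Ndufb6 (0.36, SE 0.08) among them. The list had a median of 0.21 and an adjusted p of 5.89e-09 with camera, and an adjusted p = 0.892 with an estimated correlation. With median-ratio factors 9 members rose, and with the tag as a term 1 did, at a median of 0.23. Ribosome biogenesis factors rose in 3 of 16 members (5 adjusted over the list alone), namely the nucleolar proteins Nop2 (0.35, SE 0.10), Nop56 (0.33, SE 0.10) and Dkc1 (0.25, SE 0.08), with adjusted p = 0.892 with an estimated correlation. None of these 16 rose with median-ratio factors. Leaving out control 7 ended camera's call of this list, from an adjusted p of 0.017 to 0.0936.

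Lists called lower at 1 g/L held few genes past the test. Endoplasmic reticulum (ER) chaperones fell in 2 of 14 members (3 adjusted over the list alone), Herpud1 (−1.01, SE 0.22) and Derl3 (−0.999, SE 0.263), both of ER-associated degradation, at a median of −0.28. Acute-phase genes fell in 3 of 18 (3 adjusted over the list alone), Itih3 (−0.53, SE 0.13), Itih4 (−0.62, SE 0.19) and the interleukin 1 receptor Il1r1 (−0.50, SE 0.16). Camera's adjusted p for this list was 0.00067, and 0.0534 without control 8, whose acute-phase score of 0.676 was the highest of the controls. Under the tag as a term it was 0.145 at a median of −0.13, and Itih3 (−0.53, SE 0.18), Itih4 (−0.58, SE 0.23) and Il1r1 (−0.32, SE 0.21) were no longer called, the first 2 at like folds under wider errors. Hepatocyte core genes fell in 2 of 15 (5 adjusted over the list alone), prothrombin F2 (−0.48, SE 0.07) and Apob (−0.34, SE 0.07), with 5 falls with median-ratio factors and 1 with quantile normalization, which ended camera's call (0.107). Of the 19 tested genes of cholesterol synthesis 1 is not reported here, and counts and tests of this list are over the other 18. None of these was called alone at 1 g/L (none adjusted over the list alone), at a median of −0.18 and adjusted p = 0.000758 with camera, a call that stayed with median-ratio factors (0.00238, 3 falls), quantile normalization (0.00288, 1 fall), the tag as a term (5.15e-05) and each library left out (up to 0.0125). For each of these lists the adjusted p = 0.892 with an estimated correlation.

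Other lists had calls in both directions or in no member at 1 g/L. Apolipoproteins and lipoprotein handling had 1 rise, Apoc2, and 3 falls among 20, including the receptor Lrp1 (−0.41, SE 0.06), with 1 rise and 4 falls adjusted over the list alone. Fatty acid synthesis had 1 rise, the receptor Nr1h3 (0.18, SE 0.05), and 2 falls among 19, Lpin1 and the desaturase Fads1 (−0.27, SE 0.09), the same counts as adjusted over the list alone. None of these 19 rose with median-ratio factors, quantile normalization or the tag as a term, where 3, 2 and 1 fell. Median-ratio factors ended the camera call of this list (0.0509) and of the interferon list (0.107), whose medians went from −0.12 to −0.19 and from −0.017 to −0.075 as all folds were shifted down. Kupffer cell markers (14 members, median −0.10) and interferon-response genes (27 members, median −0.02) had no member past limma's test, over all genes or over the list alone, although camera called both, at adjusted p = 0.0146 and 0.0329. The tag as a term ended camera's calls of the acute-phase, apolipoprotein, Kupffer and interferon lists at 1 g/L (0.145, 0.275, 0.275 and 0.725) and kept the other 6. The medians of the apolipoprotein, Kupffer and interferon lists were −0.04, −0.07 and −0.02 with the term, against −0.06, −0.10 and −0.02 without it. For the 4 lists of this paragraph the adjusted p = 0.892 with an estimated correlation, and leaving out 1 library ended each call, as control 8 did for Kupffer markers (0.12). PPARα targets had 1 rise and 1 fall among 36 (none adjusted over the list alone), at a median of 0.12, with Cyp4a14 at 0.86 (SE 0.40) and Cyp4a10 at 0.73 (SE 0.45).

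At 2 g/L the fat-oxidation programme rose. Cyp4a14, a microsomal fatty acid hydroxylase and classic PPARα target on chromosome 4 at 115486200 to 115496142, went from 0.925 ± 0.978 in controls to 714 ± 370 RPKM (SD, n = 6), a log2 fold of 8.42 (SE 0.40, adjusted p = 4.05e-13). Its neighbour Cyp4a10 (chromosome 4, 115518264 to 115533649) went from 3.90 ± 3.29 to 692 ± 359 RPKM (7.20, SE 0.45). Ehhadh, the peroxisomal bifunctional enzyme of β-oxidation (chromosome 16, 21761287 to 21787807), rose by 4.65 (SE 0.35), and Cyp4a31 by 3.93 (SE 0.29). The acyl-CoA thioesterases Acot1 (3.67, SE 0.38) and Acot2 (3.12, SE 0.37), the peroxisomal thiolase Acaa1b (3.29, SE 0.27) and the fatty aldehyde dehydrogenase Aldh3a2 (3.07, SE 0.31) rose too. Cyp4a genes are similar enough to share reads, so the division between them is uncertain.

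Of the 36 PPARα targets tested, 33 rose and none fell at 2 g/L (34 rose adjusted over the list alone), with a median log2 fold of 1.40 and adjusted p = 3.19e-15 with camera, and adjusted p = 0.422 with an estimated correlation. With median-ratio factors 33 rose at a median of 1.23, and with the tag as a term 31 rose at a median of 1.23. The score of this list was 1.33 ± 0.40 (SD) at 2 g/L, from 0.668 to 1.75 over the 6 libraries, against −0.006 ± 0.08 in controls. The library 2 g/L 78 stood apart, with Ehhadh at 165 RPKM where the other libraries of its dose had a mean of 1140. Fgf21, the fasting hormone induced by PPARα, rose by 0.37 (SE 0.10).

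**Figure D4:**
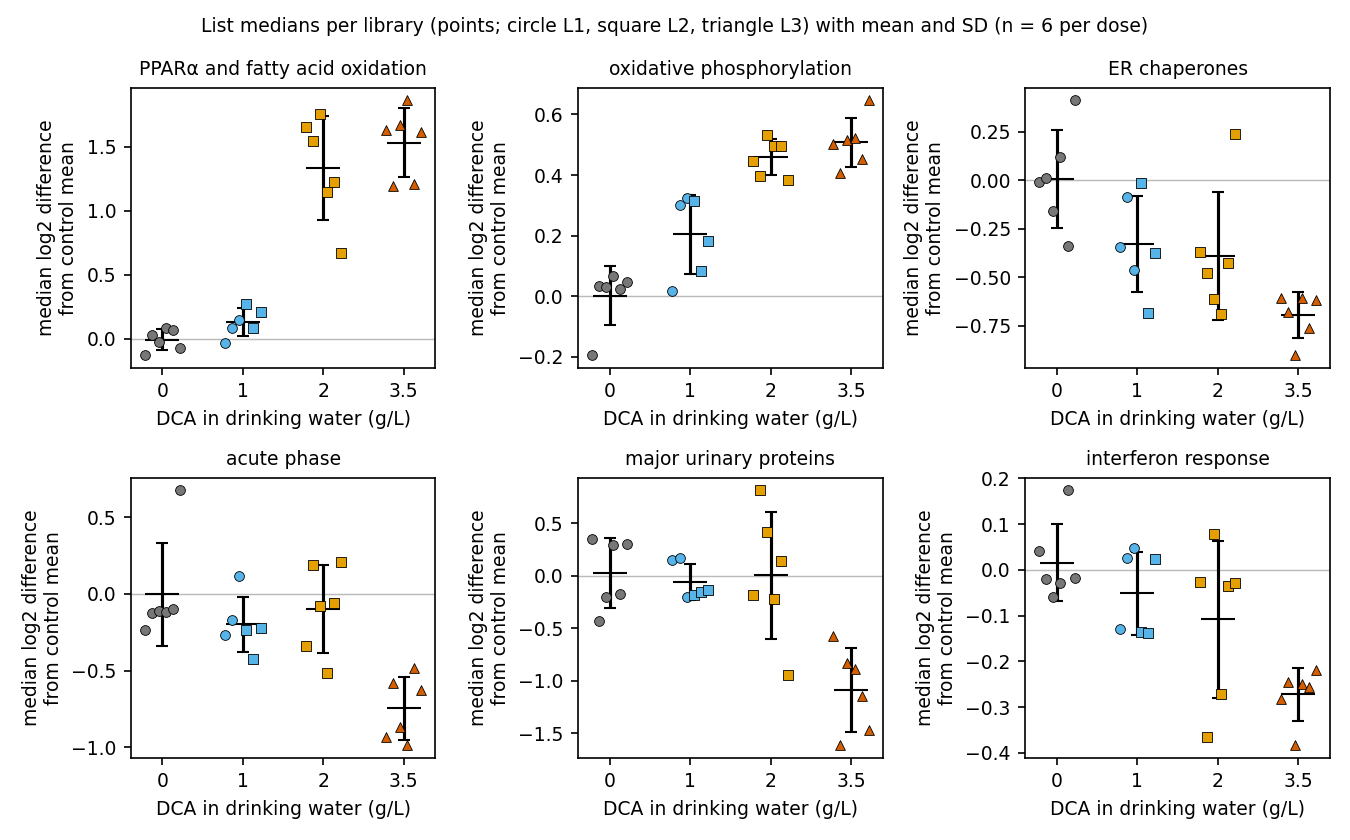
Median log2 difference from the control mean over the members of 6 gene lists, 1 point per library shaped by title tag, with the mean and SD of each dose. The PPARα list lies at −0.006 in controls and 1.53 at 3.5 g/L, and the major urinary protein list at 0.024 and −1.09.

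Mitochondrial energy genes rose at 2 g/L. Of the 52 oxidative phosphorylation genes, 49 rose and none fell (50 adjusted over the list alone), including Atp5k (0.84, SE 0.08), cytochrome c oxidase subunit Cox5b (0.77, SE 0.08) and Atp5l (0.60, SE 0.06). The median was 0.46, camera's adjusted p was 3.76e-12, and the adjusted p = 0.497 with an estimated correlation. With median-ratio factors 40 rose and with the tag as a term 35 did. Among 14 citric acid cycle genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Dlst (0.82, SE 0.09), Dld (0.42, SE 0.06) and Idh1 (0.64, SE 0.10) rising, at adjusted p = 0.68 with an estimated correlation. Median-ratio factors gave 6 rises and 2 falls there, at a median of 0.15 against 0.31 as deposited. The tag as a term gave 2 rises, with Dlst at 0.685, at a median of 0.24 under wider errors, and no call of the list (0.2). The pyruvate dehydrogenase list was drawn up for the enzyme that DCA activates and the pyruvate carriers, and only 4 of its genes were tested. Of these 4, 3 rose at 2 and at 3.5 g/L. All Pdh, Pdp and Pdk genes come after the last symbol held and were not tested, so the count does not show whether those genes changed.

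Cell cycle and antioxidant genes rose at 2 g/L as well. Cyclin D1, Ccnd1, which drives entry into the cycle, went from 4.22 ± 0.67 to 16.4 ± 4.30 RPKM (SD, n = 6; log2 fold 1.71, SE 0.17). Of 25 cell cycle genes 21 rose (21 adjusted over the list alone), with the replication helicase subunits Mcm2 (0.37, SE 0.08) and Mcm7 (0.42, SE 0.09), at a median of 0.40 and adjusted p = 0.754 with an estimated correlation. With median-ratio factors 14 rose, and with the tag as a term 1 did, at a median of 0.17, namely Ccnd1 (1.39 with the term). Antioxidant genes regulated by NRF2 had 14 rises and 1 fall among 20 (the same adjusted over the list alone), with epoxide hydrolase Ephx1 (1.74, SE 0.17), malic enzyme Me1 (1.71, SE 0.19) and Gsta2 (1.70, SE 0.21), at adjusted p = 0.67 with an estimated correlation. With the tag as a term 6 of them rose, at a median of 0.46 against 0.60 without it. Gsta and Gstm genes are near-identical and their division is uncertain.

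The largest falls at 2 g/L were in single genes of several kinds. After Lpin1 (−2.79, SE 0.19) the largest were in Cyp2c40 (−2.66, SE 0.70) and Cyp2c69 (−1.85, SE 0.53), in Hspa1b (−2.37, SE 0.27), in the urinary protein gene Mup21 (−2.05, SE 0.40) and in Elovl3, a fatty acid elongase (−1.66, SE 0.25). Herpud1 (−1.61, SE 0.22) and the carboxylesterase Ces1b (−1.54, SE 0.15) followed. Under the tag as a term Cyp2c40 (−3.61, SE 1.2, adjusted p = 0.0541), Cyp2c69 (−2.81, SE 0.94, 0.0561) and Mup21 (−1.53, SE 0.52, 0.06) were no longer called under wider errors, and the others of these 8 were kept. Cyp2c and Mup genes share reads within their families and are uncertain.

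Hepatocyte core genes fell in 8 of 15 members at 2 g/L and rose in none (8 adjusted over the list alone), with F2 (−0.94, SE 0.07) and the vitamin D-binding protein Gc (−0.56, SE 0.08), at a median of −0.31 and adjusted p = 0.422 with an estimated correlation. Apolipoproteins and lipoprotein handling had 10 falls and 4 rises among 20 (10 and 5 adjusted over the list alone), with Apoa4 (−1.14, SE 0.13) and Apoh (−0.68, SE 0.07) falling and Apoc2 rising (1.06, SE 0.08), at adjusted p = 0.422 with an estimated correlation. Male-biased genes had 7 falls and 1 rise among 22 (the same adjusted over the list alone), with complement component C8a (−0.86, SE 0.09) and Elovl3 falling and Cyp4a12b (1.67, SE 0.31) rising, at adjusted p = 0.422 with an estimated correlation. With median-ratio factors, where falls were also a larger share of the calls over all genes, 12 of the male-biased genes fell and 1 rose. With the tag as a term 2 fell and 1 rose, at a median of −0.16 against −0.29 without it, and camera's adjusted p was 0.0915. ER chaperones had 7 falls, as in the lectin chaperone Canx (−0.33, SE 0.06), and 1 rise, Dnajc10 (0.40, SE 0.08), the same adjusted over the list alone, at adjusted p = 0.497 with an estimated correlation. With the tag as a term 2 of them fell, with Herpud1 at −2.01, and the list stayed called (median −0.30 against −0.36 without it, adjusted p = 0.00826 with camera).

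Immune and blood genes were lower at 2 g/L in part. Interferon-response genes had 9 falls and 1 rise among 27 (8 and none adjusted over the list alone), with Ifit1 (−0.56, SE 0.10), Irf7 (−0.70, SE 0.14) and Oas2 (−0.39, SE 0.07), at adjusted p = 0.512 with an estimated correlation. With median-ratio factors, where falls were also a larger share of the calls over all genes, 12 of the interferon-response genes fell and none rose. With the tag as a term none of them fell, while the median stayed at −0.07 and Ifit1 was at −0.50 (SE 0.18). Acute-phase genes had 5 falls among 18 (4 adjusted over the list alone), with Il1r1 (−1.03, SE 0.16), Itih4 (−0.80, SE 0.19) and Itih3 (−0.61, SE 0.13), at adjusted p = 0.569 with an estimated correlation, and none fell with the tag as a term, where the median was 0.03 against −0.18 without it and Itih3 was at −0.60 (SE 0.26). Erythroid genes had 7 falls and 1 rise among 10 (the same adjusted over the list alone), with the haem synthesis enzyme Alas2 (−0.82, SE 0.16) and Hbb-b2 (−0.90, SE 0.27) falling and carbonic anhydrase Car2 (0.50, SE 0.12) rising, at adjusted p = 0.497 with an estimated correlation, and none was called with the tag as a term, at a median of −0.48 against −0.76 without it. Globin genes are near-identical and uncertain.

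Genes of liver zones and of other cell types were called lower at 2 g/L with few members. Pericentral genes had 7 falls, led by Cyp1a2 (−1.01, SE 0.10) and Gulo of vitamin C synthesis (−0.53, SE 0.07), and 4 rises, with Aldh3a2 and Cyp7a1 among them, out of 17 (the same adjusted over the list alone). The median was −0.09 and the mean 0.13 while camera's direction was down, at adjusted p = 0.422 with an estimated correlation. Periportal genes had 5 falls, with Cps1 of the urea cycle (−0.63, SE 0.09), and 2 rises, with Aldh1b1 (0.77, SE 0.09), out of 17 (the same adjusted over the list alone), also at 0.422, and 11 falls and 2 rises with median-ratio factors. One-carbon and glycine genes had 6 falls, as in Dmgdh (−0.69, SE 0.10) and Ahcy (−0.52, SE 0.07), and 4 rises, as in Grhpr (0.67, SE 0.09), out of 19 (7 and 4 adjusted over the list alone), with a median of 0.01 and a mean of −0.03 where camera's direction was down, at adjusted p = 0.542 with an estimated correlation. Urea cycle genes had 3 falls, including Oat (−0.30, SE 0.10), and 1 rise, Nags (0.27, SE 0.07), among 9, at adjusted p = 0.539. With median-ratio factors 5 of them fell and 0 rose, and with the tag as a term 1 fell and 0 rose. Stellate cell markers had 2 falls, Col6a1 (−0.32, SE 0.10) and Ecm1 (−0.27, SE 0.09), and 2 rises with Acta2 (0.48, SE 0.15), among 10, at adjusted p = 0.584, and median-ratio factors ended camera's call (0.0798) with 5 falls and 1 rise. Sinusoidal endothelial markers had 1 fall among 11, Gpr182 (−0.21, SE 0.07), at adjusted p = 0.497, and 7 falls with median-ratio factors. Falls were also a larger share of the calls over all genes under those factors, so higher fall counts with them do not by themselves set a list apart. Major urinary proteins had 2 falls, as in Mup3 (−0.40, SE 0.13), and 1 rise, Mup2 (1.05, SE 0.36), among 19 (1 and none adjusted over the list alone), at adjusted p = 0.631 with an estimated correlation and, from camera, 0.467 with median-ratio factors at a median of −0.19 against −0.03 as deposited. The p-values of these last lists are camera's with an estimated correlation, and leaving out 1 library ended the camera calls of the one-carbon, urea cycle, stellate, sinusoidal, urinary protein and citric acid cycle lists, up to 0.193 for the urinary proteins. With the tag as a term camera called 6 lists at 2 g/L, the PPARα, oxidative phosphorylation, hepatocyte core, ER chaperone, NRF2 and periportal lists.

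At 3.5 g/L the PPARα programme was fully called. All 36 targets rose (36 adjusted over the list alone), with a median of 1.51 and adjusted p = 9.06e-19 with camera, and adjusted p = 0.325 with an estimated correlation. With median-ratio factors 35 rose at a median of 1.37. Cyp4a14 reached 1120 ± 305 RPKM (SD, n = 6; log2 fold 9.26, SE 0.40, adjusted p = 4.63e-14), Cyp4a10 rose by 7.96 (SE 0.45), Ehhadh by 5.22 (SE 0.35) and Cyp4a31 by 4.77 (SE 0.29). Acot1 (4.98, SE 0.38), Acot4 (3.09, SE 0.19) and Acot3 (4.91, SE 0.32) rose, with Acot3 going from 0.0501 ± 0.0263 to 34.0 ± 17.6 RPKM. The tag L3 marks this dose alone, so the tag and the dose cannot be told apart for any value at 3.5 g/L.

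Genes expressed more in female liver were among the largest rises at 3.5 g/L. Cyp2a4, a steroid hydroxylase (4.79, SE 0.32), and Cyp2b9 (4.53, SE 0.38) rose, on chromosome 7 at 26307169 to 26315088 and 26173411 to 26210661. The female-biased list had 7 rises and 3 falls among 11 (the same adjusted over the list alone), with a median of 1.91 and adjusted p = 0.498 with an estimated correlation. Its members Cyp4a10, Cyp4a14 and Acot3 are PPARα targets as well, and Cyp2c40 fell (−2.86, SE 0.70). Male-biased genes fell in 14 of 22 members and rose in 1 (the same adjusted over the list alone), with Elovl3 (−2.69, SE 0.25), Mup21 (−2.88, SE 0.40) and the oxysterol hydroxylase Cyp7b1 (−2.09, SE 0.22), at a median of −0.73 and adjusted p = 0.284 with an estimated correlation. Major urinary protein genes fell in 14 of 19 and rose in none (14 adjusted over the list alone), with Mup12 (−1.48, SE 0.26), Mup9 (−2.05, SE 0.69) and Mup3 (−0.66, SE 0.13), at a median of −1.08 and adjusted p = 0.325 with an estimated correlation.

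Several lists of immune and plasma-protein genes had many falls at 3.5 g/L, while camera did not call the antigen presentation list (adjusted p = 0.0516). Complement component C9 went from 282 ± 86.8 to 44.9 ± 15.7 RPKM (SD, n = 6; log2 fold −2.65, SE 0.19) and C4b from 153 ± 22.7 to 37.9 ± 8.06 RPKM (−1.995, SE 0.118). Acute-phase genes fell in 13 of 18 and rose in none (13 adjusted over the list alone), with Itih3 (−1.24, SE 0.13), Itih4 (−1.44, SE 0.19) and the metallothionein Mt2 (−2.14, SE 0.79), at a median of −0.74 and adjusted p = 0.325 with an estimated correlation. Interferon-response genes fell in 17 of 27 (17 adjusted over the list alone), with the GTPase Ifi47 (−0.82, SE 0.12), Ifit1 (−0.65, SE 0.10) and Oas2 (−0.44, SE 0.07), at adjusted p = 0.334 with an estimated correlation. Kupffer cell markers fell in 12 of 14 (12 adjusted over the list alone), with the lectin Clec4f (−0.55, SE 0.10), complement C1qb (−0.56, SE 0.13) and the Fc receptor Fcgr1 (−0.24, SE 0.06), at a median of −0.38 and adjusted p = 0.418 with an estimated correlation. Hepatocyte core genes fell in 11 of 15 and rose in 1 (11 and 2 adjusted over the list alone), with F2 (−1.02, SE 0.07), Ambp (−0.84, SE 0.09) and Apob (−0.63, SE 0.07), at adjusted p = 0.284 with an estimated correlation.

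Rises at 3.5 g/L were also called in lists of energy metabolism, glutathione S-transferases and the p53 response. All 52 oxidative phosphorylation genes rose (52 adjusted over the list alone), with Cox5b (0.88, SE 0.08), Cox7c (0.76, SE 0.07) and Atp5l (0.66, SE 0.06), at a median of 0.52 and adjusted p = 0.418 with an estimated correlation, and 46 rose with median-ratio factors. Citric acid cycle genes rose in 10 of 14, as in Mdh2 (0.50, SE 0.07), and fell in none (10 adjusted over the list alone), at adjusted p = 0.6 with an estimated correlation. Glutathione S-transferases had 15 rises and 2 falls among 21 (the same adjusted over the list alone), with Gsta1 (2.56, SE 0.24), Gsta2 (2.50, SE 0.21) and Gstm1 (1.48, SE 0.16), at adjusted p = 0.621 with an estimated correlation. The NRF2 list, which shares those transferases, had 14 rises and 2 falls among 20 (15 and 2 adjusted over the list alone), with Me1 (2.04, SE 0.19) and Ephx1 (2.05, SE 0.17), at adjusted p = 0.552 with an estimated correlation. Genes of the p53 response rose in 8 of 11, as in the nuclease Aen (0.74, SE 0.06) and Gadd45a (0.53, SE 0.08), with 8 adjusted over the list alone, while Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was at −0.49 (SE 0.26) and not called. The p53 list was at adjusted p = 0.418 with an estimated correlation, and leaving out any of 6 libraries ended camera's call, up to 0.0634.

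ER chaperones fell in 11 of 14 and rose in none at 3.5 g/L (11 adjusted over the list alone), with Herpud1 (−1.58, SE 0.22), calreticulin Calr (−0.81, SE 0.12) and Canx (−0.47, SE 0.06), at a median of −0.74 and adjusted p = 0.334 with an estimated correlation. Cholesterol synthesis had 9 falls, with Mvk (−0.97, SE 0.11) and Fdps (−0.84, SE 0.15), and 3 rises, with Hsd17b7 (0.67, SE 0.11), among 18 (the same adjusted over the list alone), at adjusted p = 0.594 with an estimated correlation. Erythroid genes had 5 falls, with Alas2 (−1.20, SE 0.16), and 1 rise, Car2 (0.49, SE 0.12), among 10 (7 and 1 adjusted over the list alone), at adjusted p = 0.552 with an estimated correlation. Pericentral genes had 7 falls, with Cyp1a2 (−1.13, SE 0.10), and 4 rises, at a median of −0.07 and a mean of 0.18 where camera's direction was down, and periportal genes had 8 falls, with Cdh1 (−0.45, SE 0.07), and 4 rises, each among 17. Their adjusted p was 0.446 and 0.552 with an estimated correlation. With median-ratio factors the camera calls of the erythroid, pericentral and periportal lists ended (0.0741, 0.0741 and 0.0671) although their falls did not shrink, at medians of −0.83, −0.22 and −0.21 with 7, 8 and 8 falls against −0.68, −0.07 and −0.06 as deposited, and leaving out 3.5 g/L 101 ended that of the periportal list (0.0578). Cell cycle genes had 5 rises among 25 (1 adjusted over the list alone) and no camera call, with Ccnd1 at 1.26 (SE 0.17). Lpin1 was at −2.56 (SE 0.19), and Nr1d1 rose by 2.90 (SE 0.165) after 2.33 (SE 0.165) at 2 g/L.

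Genes named in advance for their part in DCA metabolism and liver fuel use moved to different degrees. Gstz1, the enzyme that breaks DCA down (chromosome 12, 87147165 to 87164723), was at 117 ± 7.85, 131 ± 7.95, 129 ± 8.99 and 123 ± 4.87 RPKM (SD, n = 6) over 0, 1, 2 and 3.5 g/L. Its rise at 2 g/L (0.14, SE 0.06) was called as deposited and turned to −0.03 with median-ratio factors. Fasn, fatty acid synthase, was at −0.36 (SE 0.21, not called) at 1 g/L and rose by 0.95 (SE 0.21) at 2 g/L and 1.42 (SE 0.21) at 3.5 g/L, with 0.35 and no call at 2 g/L with the tag as a term. Fatty acid synthesis genes had 12 rises and 3 falls among 19 at 2 g/L (12 and 3 adjusted over the list alone) and 12 and 2 at 3.5 g/L (13 and 2), and camera did not call the list (0.215 and 0.0581). With median-ratio factors it called the list at both doses (0.0469 and 0.0133), with quantile normalization at 3.5 g/L alone (0.0634 and 0.0138), and leaving out any of 5 libraries also gave a call at 3.5 g/L, down to 0.0306. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.5 (SE 0.32) and 1.03 (SE 0.32) at 2 and 3.5 g/L, and at 2 g/L it stood at 1.51 (SE 0.52) with the tag as a term and was no longer called (adjusted p = 0.0615). G6pc, glucose-6-phosphatase, fell at 1 g/L (−0.68, SE 0.20), which the tag as a term ended (−0.47, SE 0.26, adjusted p = 0.385), and was not called at the other doses. Fgf21 rose by 0.63 (SE 0.10) at 3.5 g/L.

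Other genes named in advance showed smaller changes or none that passed limma's test. Cyp3a11 rose at 3.5 g/L (0.66, SE 0.23, adjusted p = 0.0201), and median-ratio factors ended that call (0.0612). Cyp2b10, the usual marker of the receptor CAR, was at −0.13, −0.21 and −0.18 (SE 0.17 each) over the doses and was not called. The list of CAR targets had 10 rises and 5 falls among 18 at 3.5 g/L (10 and 5 adjusted over the list alone), at a median of 0.915, and was called by camera with median-ratio factors (0.0472) and quantile normalization (0.0338) but not as deposited (0.355). Median-ratio factors also added calls of the histone and p53 lists at 2 g/L (0.0206 and 0.0199) and of the sinusoidal list at 3.5 g/L (0.0131). Mki67, the Ki-67 proliferation marker, rose at 2 g/L (0.54, SE 0.23, adjusted p = 0.0497), was no longer called with median-ratio factors (0.12) or with the tag as a term (0.11, adjusted p = 0.846), and was at 0.27 at 3.5 g/L. Cyp1a1 and Gadd45b were below the filter, with mean RPKM in controls of 0.198 and 0.249. Pdk1, Pdk2, Pdk4, Pck1, Srebf1 and Scd1 were not analysed here.

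The differences between doses were tested directly. Between 1 and 2 g/L, 1855 genes were called (1487 rose, 368 fell), led by Cyp4a14 (7.56, SE 0.40), Cyp4a10 (6.47, SE 0.45) and Ehhadh (4.31, SE 0.35). All 36 PPARα targets rose over that step (median 1.16, adjusted p = 0.282 with an estimated correlation), and 39 of 52 oxidative phosphorylation genes did (42 adjusted over the list alone). Its largest falls were in Cyp2c40 (−2.43, SE 0.70), Mup21 (−2.16, SE 0.40) and Cyp2c69 (−1.66, SE 0.53). Within L2, where 3 libraries of 1 g/L and 6 of 2 g/L share a tag, 589 genes were called and 568 of these were among the 1855. Median-ratio factors made rises 52.7% of the calls, against 80.2% as deposited.

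Between 2 and 3.5 g/L, 675 genes were called (313 rose, 362 fell), with the largest rises in Acot3 (3.14, SE 0.32), Cyp2a4 (2.81, SE 0.32) and Cyp2b9 (2.52, SE 0.38). Lcn2, an acute-phase protein (−3.10, SE 0.78), and the urinary protein genes Mup17 (−1.99, SE 0.49) and Mup16 (−1.97, SE 0.42) had the largest falls. PPARα targets rose in 8 of 36 members over this step (12 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation), and no oxidative phosphorylation gene was called by limma. Acute-phase genes fell in 10 of 18 (10 adjusted over the list alone), at a median of −0.64 and adjusted p = 0.436 with an estimated correlation, major urinary protein genes in 8 of 19 (11), at −0.93 and 0.436, and Kupffer markers in 7 of 14 (13), at 0.465. Cell cycle genes fell in 6 of 25 (6 adjusted over the list alone), at adjusted p = 0.633 with an estimated correlation. The doses carry different tags, L2 and L3, so tag and dose cannot be told apart here. Fitting only these groups gave 446 calls.

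From 1 to 3.5 g/L, 2214 genes were called (1583 rose, 631 fell), led by Cyp4a14 (8.41, SE 0.40), Cyp4a10 (7.23, SE 0.45) and Acot3 (4.91, SE 0.32), with falls in Mup21 (−2.99, SE 0.40), Cyp2c40 (−2.63, SE 0.70) and Elovl3 (−2.47, SE 0.25). A linear slope on dose was called for 3309 genes (2488 rising, 821 falling). Cyp4a14 rose by 2.99 per g/L (SE 0.28), Cyp4a10 by 2.57 (SE 0.25) and Ehhadh by 1.69 (SE 0.18), while Mup21 fell by 0.93 per g/L (SE 0.13), Cyp2c40 by 0.93 (SE 0.20) and Elovl3 by 0.83 (SE 0.08). With median-ratio factors 52.4% of the calls between 1 and 3.5 g/L and 50.8% of the slopes were rises, against 71.5% and 75.2% as deposited.

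Fold changes at 2 and 3.5 g/L went together. Across genes, which are not independent replicates, they correlated at r = 0.876, against 0.178 to 0.769 (mean 0.481) in simulations of unchanged groups with the same controls and 0.812 with split controls, and their covariance was 0.145 against at most 0.0123 simulated. Of the called genes 2073 rose and 471 fell at both doses, and 5 went opposite ways. For 1 and 2 g/L r was 0.567, within the simulated 0.161 to 0.777 (0.435 with split controls), while the covariance of 0.0382 was above the simulated maximum of 0.0136, with 502 shared rises and 150 shared falls. For 1 and 3.5 g/L r was 0.472, within the simulated 0.194 to 0.899 (0.366 with split controls), and the covariance of 0.0388 was above 0.0127, with 476 shared rises and 141 shared falls. Shared controls raise such counts, which are given without an expected number. The simulations centre each dose first, and the split controls all carry L1. An offset of the controls by tag or scaling, which would also make folds go together, is thus not covered. Genes that rose at both 2 and 3.5 g/L include Cyp4a14, Ehhadh and Ccnd1, and genes that fell at every dose include Lpin1, C4b and F2.

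The title tag was compared at 1 g/L, the one dose with libraries of 2 tags. Between L2 and L1, with 3 libraries each, limma called 0 of 6540 genes, with 543 at an unadjusted p under 0.05 and a median log2 difference of 0.06. In simulated data of that size 75% of 1.5-fold and 95% of 2-fold changes were recovered, seeded only in genes with a mean log2(RPKM + 1) above 1. Most dose calls were smaller, since 43 of 744 at 1 g/L and 455 of 3395 at 2 g/L reached 1.5-fold. Tag effects of that smaller size were not simulated, so 0 calls do not exclude them. The PPARα list was 0.12 higher in L2 than in L1 (SE 0.06), against 1.40 (SE 0.15) at 2 g/L over control.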

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

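The tests of the PPARα list at 2 g/L against the tag and against scaling, of the share of rises against scaling, and both tests of the clock genes were chosen only after their results were seen.

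Single libraries stood apart from the other 5 of their dose in 38 of 472 sets (118 genes at 4 doses), or 8.1%, by Dixon's test on log2(RPKM + 1). Values below are RPKM. That test finds about 1 set in 20 by chance, so many of these values are within what chance gives, and the mean of the other 5 libraries follows each value. In control 8, Lcn2 was at 153 RPKM (others 3.85), C1qb at 18.6 (12.5), Calr at 414 (290) and Gstm1 at 115 (210). In control 3, Ahcy was at 265 (316), Ces1b at 93.9 (53), F2 at 416 (452), Gc at 1340 (1530), Ndufb6 at 21 (27.7) and Oas2 at 1.11 (0.635). Nags in control 4 was at 11.4 (14.4), Col6a1 in control 5 at 3.63 (1.93) and Mup2 in control 7 at 27 (20.8). In 1 g/L 49, Lpin1 was at 3.87 (8.71), Cps1 at 615 (717), Dld at 20.9 (24.8), Dlst at 30.3 (37.9), Fads1 at 49.2 (60.7), Idh1 at 60.5 (75.7) and Ndufb6 at 25.8 (36.3). In 1 g/L 54, Cyp2a4 was at 1.44 (0.214), Cyp3a11 at 1360 (530) and Mup21 at 43.9 (102). In 1 g/L 51, Mt2 was at 23.6 (1.12) and Clec4f at 24.9 (20.3), and Herpud1 in 1 g/L 52 was at 95.6 (56.8). In 2 g/L 78, Ehhadh was at 165 (1140), Acaa1b at 259 (899), Calr at 310 (191), Dlst at 42.4 (58.2), Elovl3 at 28.8 (78.6) and Mup12 at 358 (884). Clec4f in 2 g/L 76 was at 14.2 (21.1) and Mdh2 in 2 g/L 77 at 64.1 (50.9). Cyp2b10 in 3.5 g/L 97 was at 1.15 (0.25), Acot1 in 3.5 g/L 98 at 43.3 (95.9), and in 3.5 g/L 99 Cox7c was at 175 (144) and Cyp2c69 at 3.53 (0.355). The libraries with most of them were 1 g/L 49 with 7, control 3 and 2 g/L 78 with 6 each and control 8 with 4, and no explanation was tested for them.

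The PPARα list was higher at 2 g/L by a median of 1.4 (SE 0.15 by resampling libraries). Against the tag as the whole cause, the list was only 0.119 (SE 0.06) higher in L2 than in L1 within 1 g/L, and 1.1 (SE 0.15) higher at 2 than at 1 g/L within L2. Against scaling as the whole cause, the median was 1.23 with median-ratio factors. At 3.5 g/L the rise of 1.51 cannot be told apart from the tag, because L3 marks that dose alone. An effect of the dose is a candidate explanation for the rise at 2 g/L, as a hypothesis found and tested on the same data.

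Rises were 80.6% of the calls at 2 g/L as deposited and 50.2% with median-ratio factors, but these factors centre the median fold, which by itself brings the share near 50%, so scaling as the cause is neither shown nor excluded. The 20 most abundant genes held took 14.5% of reads in controls (SD 0.9) and 11.2% at 2 g/L (SD 1.3), which would lift all others by 0.0534 (SE 0.0096) on the log2 scale against a median shift of 0.118. That is below the whole shift, while 0.5 of it (0.0592) is within the error, so reads released by these genes stay open as a part of the cause. Albumin, Alb, whose values were seen before it was singled out, took 5.01% in controls and 3.53% at 2 g/L. The controls are all L1 and 2 g/L is all L2, and within 1 g/L L2 lay above L1 by a median of 0.058. The tag therefore also stays open as a part of the shift. A real rise in many genes relative to total RNA was not tested, since the labels name no added RNA standard.

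Of 12 clock genes tested, 2 rose and 1 fell at 1 g/L, 3 rose and 1 fell at 2 g/L, and 7 rose and 4 fell at 3.5 g/L, with 2 and 1, 2 and 3, and 4 and 4 with median-ratio factors, no camera call (0.898, 0.602 and 0.923), and Nr1d1 called at 0.992, 2.33 and 2.90 (SE 0.165). Dbp at 1.85 (SE 0.38) and Arntl at −0.935 (SE 0.205) were called at 3.5 g/L, and both were chosen after their values were seen. The rise of Nr1d1 at 1 g/L was beyond the median of 0.115 of the PPARα list there. Single targets on that list, Cyp4a14 (0.858, SE 0.399) and Cyp4a10 (0.733, SE 0.454), stood at like values without a call. The list's median therefore cannot tell whether Nr1d1 followed the PPARα response, which stays open. If collection times differed within doses, Dbp and Arntl should move against each other, and as deviations from dose means they gave r = −0.852 over 24 libraries (permutation p = 1e-05, the smallest possible, adjusted 4e-05) and rho = −0.502 (permutation p = 0.0133, adjusted 0.0267), with r = −0.588 without 3.5 g/L 98 and 100. By tag r was −0.175 in L1 (n = 9, exact p = 0.648, adjusted 0.864, rho −0.2) and −0.059 in L2 (n = 9, exact p = 0.88, rho 0.033). In L3 r was −0.977 (n = 6, exact p = 0.00139, adjusted 0.00278) and rho −1 (exact p = 0.00278). These were 4 relations in all, and the relation seen rests on the 3.5 g/L libraries. In every control and 1 g/L library Dbp was at 0.137 to 0.312 RPKM, under the filter level of 0.5 RPKM. A relation could therefore hardly show in L1, and the r of L1 cannot decide. Collection time, which the labels do not state, may or may not differ between doses and stays open.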

How the results depend on the processing

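List counts under quantile normalization and with the tag as a term were chosen after seeing the data, and other alternatives were planned. Counts of called genes stayed within 1.5 times for every comparison with a pseudocount of 0.1 RPKM, no filter, a filter of 2 RPKM, median-ratio factors, quantile normalization and a robust spread, at 564 to 775 for 1 g/L, 2674 to 3400 for 2 g/L and 2828 to 3432 for 3.5 g/L. A minimum fold of 1.5, which by construction removes small changes, left 43, 455 and 614 genes at 1, 2 and 3.5 g/L, 269 between 1 and 2 g/L, 103 between 2 and 3.5 g/L, 420 between 1 and 3.5 g/L and 674 slopes. The tag as a term over 0, 1 and 2 g/L, which leaves out 3.5 g/L and rests on the 1 g/L libraries to part tag from dose, left 92 genes at 1 g/L (91 among the 744), 864 at 2 g/L (832 among the 3395), 837 between 1 and 2 g/L (808 among the 1855) and 729 slopes (655 among the 3309). With fewer libraries, within L1 50 genes were called at 1 g/L, and within L2 589 between 1 and 2 g/L. Fitting only the groups compared gave 446 genes between 2 and 3.5 g/L. Camera with an estimated correlation called 0, 0 and 0 lists at 1, 2 and 3.5 g/L, with 0, 4 and 5 at an unadjusted p under 0.05. Fry called 0, 27 and 31 lists with members moving 1 way on balance, and 17, 37 and 39 in either direction, which does not compare a list with other genes. Quantile normalization gave 6 lists at 1 g/L, and the tag as a term 6 at 1 g/L and 6 at 2 g/L. Except where construction is named, the cause was not tested.

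With 1 library left out, counts at 1 g/L beyond 1.5 times were 456 (without control 3), 476 (without 1 g/L 52) and 484 (without 1 g/L 54). Leaving out 1 library in turn gave 456 to 971 genes at 1 g/L, the highest without 1 g/L 49. It gave 3050 to 3387 at 2 g/L, 3140 to 3307 at 3.5 g/L, 1445 to 1945 between 1 and 2 g/L, 465 to 654 between 2 and 3.5 g/L, 1923 to 2186 between 1 and 3.5 g/L, 3153 to 3349 slopes, and 8 to 12, 15 to 21 and 17 to 22 lists. Correlations of fold changes between doses stayed at 0.457 to 0.877 with median-ratio factors and a pseudocount of 0.1 RPKM.

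Of the 118 genes, 40, 98 and 100 were called at 1, 2 and 3.5 g/L. With the tag as a term 14 of the 40 and 50 of the 98 kept their call in the same direction, while 26 and 48 lost it. Median-ratio factors kept 33, 91 and 95 of these calls and added 8, 2 and 2. Genes that reversed were not called in the alternative, and the cause was not tested. With the tag as a term at 1 g/L, Acot2 was at −0.0421, Acot3 at −0.0136, Alas2 at 0.0807, C1qb at 3.54e-05, Ccnd1 at −0.00715, Cyp2a4 at −0.238, Dnajc10 at −0.0826, Ecm1 at 0.048, Mki67 at −0.0399 and Mup16 at 0.0137. At 2 g/L, C1qb was at 0.133, Cyp3a11 at −0.581, Fcgr1 at 0.0274, G6pc at 0.42 and Mt2 at 0.164. With median-ratio factors Acot2 was at −0.00413, Cyp2a4 at −0.0228, Dnajc10 at −0.0541, Grhpr at −0.0215 and Mdh2 at −0.00953 at 1 g/L. Under those factors Cyp3a11 was at −0.132, Gstz1 at −0.0289, Mup16 at −0.101 and Mup17 at −0.0149 at 2 g/L, and Dnajc10 at −0.043, Gstz1 at −0.0702, Mcm2 at −0.0438 and Mcm7 at −0.0577 at 3.5 g/L. With a pseudocount of 0.1 RPKM, Cyp2a4 was at −0.199 at 1 g/L. Alternatives planned for a table of read counts could not be run, since the values held are RPKM. Depth limits short genes near 0.5 RPKM, where few reads make up the value, and genes below the filter were not tested.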

Other observations

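The tests of the complement and coagulation list and of the carboxylesterase list were chosen only after their genes were seen among the falls.

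Complement and coagulation genes, plasma proteins made by hepatocytes, fell as a group. Of 36 tested members of a list assembled after C3, C4b, C9 and F5 had been seen, 17 fell at 1 g/L, 31 at 2 g/L and 35 at 3.5 g/L, and none rose. Without those 4 genes 14, 27 and 31 of 32 fell (96.9% at 3.5 g/L). These 32 still hold F2 and C8a, named above among the falls of fixed lists, so they are not a check on unseen genes alone. At 3.5 g/L the median was −0.853, with C9 (−2.65, SE 0.19), C8b (−1.76, SE 0.12), F11 (−1.51, SE 0.11), F5 (−1.27, SE 0.07) and C3 (−0.93, SE 0.13), and Mbl2 was at 0.21 and not called. Over 3 such lists and without the 4 genes camera's adjusted p = 0.0359, 0.00277 and 0.00206 with an estimated correlation at 1, 2 and 3.5 g/L, and 20, 34 and 35 of all 36 fell with median-ratio factors. At 3.5 g/L the dose cannot be told apart from the tag. At 1 and 2 g/L none of the 3 lists was run with the tag as a term, and none was run with single libraries left out at any dose. Their p-values are adjusted over these 3 lists alone and cannot be set beside those of the 43 fixed lists.

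Carboxylesterases, which hydrolyse esters and many drugs, had 8 falls and 2 rises among 14 at 3.5 g/L, and 7 falls and 3 rises at 2 g/L, counting Ces1b, Ces2a and Ces3b, which prompted the list. Without these 3, 5 of 11 fell (45.5%) and 2 rose at 3.5 g/L, at a median of −0.006, and 4 fell and 3 rose at 2 g/L, so a fall of the family as a set is not shown. At 3.5 g/L, Ces4a (−1.75, SE 0.14), Ces3b (−1.66, SE 0.155), Ces2a (−1.35, SE 0.15) and Ces1c (−1.16, SE 0.12) fell, while Ces1f (0.57) and Ces1g (0.66) rose. Without the 3 genes the adjusted p = 0.124 and 0.117 at 3.5 and 2 g/L with an estimated correlation (0.0334 and 0.0414 with them), and 0.699 at 1 g/L. Ces genes lie side by side and are similar, so the division of reads between them is uncertain.

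Mitochondrial ribosomal protein genes, whose list was assembled after the oxidative phosphorylation list was seen to rise, rose in 17, 71 and 67 of 76 members at 1, 2 and 3.5 g/L (88.2% at 3.5 g/L) and fell in none. Mrps18b (0.84, SE 0.09), Mrpl50 (0.58, SE 0.05) and Mrpl45 (0.58, SE 0.07) rose at 3.5 g/L. With median-ratio factors 12, 52 and 48 rose, and with an estimated correlation the adjusted p = 0.197, 0.0834 and 0.139.

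Other splits of the same libraries were counted, with 100 splits each including the real one. For genes called, 1 of the 100 splits, the real one, reached the real count in each comparison. That share is the smallest that 100 splits can give and is not adjusted over the comparisons, so chance is unlikely rather than excluded. At 2 and 3.5 g/L against control, and between 2 and 3.5 g/L, the real split is also the split by tag. Between 1 and 3.5 g/L the real split also parts L3 from L1 and L2. The real counts and the highest of the other splits were 744 and 418 at 1 g/L, 3395 and 1752 at 2 g/L, 3368 and 1949 at 3.5 g/L, 1855 and 760 between 1 and 2 g/L, 675 and 60 between 2 and 3.5 g/L, 2214 and 780 between 1 and 3.5 g/L, and 3309 and 1 for slopes. For camera's lists 4 of the 100 splits gave as many at 2 g/L (real 19, highest other 21). This share is only just under 0.05 and is not adjusted for 3 doses, so chance is not excluded there. Camera called 0 lists with an estimated correlation. Chance is not excluded for the lists at 1 g/L, with 32 of the 100 (real 10, highest other 18), or at 3.5 g/L, with 12 of the 100 (real 18, highest other 24). For the tag within 1 g/L there are 10 splits, too few for a share under 0.05, with 0 genes called by limma in the real split (543 at an unadjusted p under 0.05), a highest other of 0, and 10 of the 10 splits at that count.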
